A study of Mus musculus with 2 samples.

How the data were processed

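Long-read RNA sequencing was done on adrenal glands of male B6CASTF1/J mice aged 36 days, the first-generation cross of the C57BL/6J and CAST/EiJ inbred strains. The study has 1 group and 2 libraries, named replicate 1 and replicate 2 after the biological replicate number in the labels, so no condition is compared with another. One label field gives both libraries the same animal number and another gives them different numbers. Whether they came from separate animals is therefore not certain, and the spread between them may be partly technical.

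Per the labels' protocols, the reads went through a standard long-read pipeline for mouse. Per the file headers and attributes, the authors assigned each read to a transcript model of the GENCODE M21 annotation on the mm10 genome, or to an unannotated model, and deposited whole read counts per model and library with no normalization. The columns are those of TALON, a program that sorts long reads into classes. Known reads follow an annotated transcript. An incomplete splice match (ISM) follows part of one. A NIC transcript joins annotated splice sites in a combination that is not annotated, and an NNC transcript has at least 1 splice site that is not annotated. Genomic reads overlap a gene without its splicing, Antisense reads lie opposite a gene, and Intergenic reads lie outside genes. The deposited tables list no model with 0 reads. Versions of the aligner and of TALON are not given in the sources used here. The deposited length column, in bases, is the length of the model and not of each read: a Known model has its annotated length, and an unannotated single-exon model can collect reads of different lengths. Read lengths were not analysed here.

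The 2 tables held 458001 and 479002 reads, of which 452489 and 463210 were endogenous. Spike-in reads were left out of all totals. Levels were expressed as CPM, the usual scaling of counts by the library total, over endogenous reads, so 1 read was worth 2.21 CPM in replicate 1 and 2.16 CPM in replicate 2, and a count of 0 allowed up to 6.63 and 6.48 CPM (a floor of 3 counts). Reads were summed per annotated gene over every class. Gene positions were taken from the M21 primary assembly annotation, since 16004 of 55536 genes had another span in the authors' model file of replicate 1. Shares of reads carry Wilson 95% intervals. Ratios of counts carry exact conditional 95% intervals. Intervals, floors, the p-values of Fisher's exact test and the chi-square of the libraries cover the counting error of independent reads only, not variation between samples. Reads amplified without molecular identifiers are not independent molecules, so the counting error itself may be larger.

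Each gene with at least 10 reads summed over both libraries was tested with a two-sided Fisher's exact test on its reads and the remaining reads, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold after adding 1 CPM. Such a test on the reads of 2 libraries compares these libraries, not conditions. Each gene list was described by the median log2 ratio of its tested members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to lie outside the random lists when its percentile is outside the middle 95%. A version matched also on transcript length used 5 length bins. No p-value was given to a list. edgeR supplied the TMM factors (1.02 and 0.977) and the common dispersion of an intercept-only design. DESeq2 supplied size factors, used only as an alternative scale.

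Splice forms were compared within the full-length classes, Known, NIC and NNC. Unannotated forms were matched between the libraries by chromosome, strand and intron chain. The share of the leading form was taken over genes with at least 50 full-length reads in each library. Its change was tested with Fisher's exact test and called at an adjusted p under 0.05 and at least 10 percentage points. A gene counted as led by an unannotated form when a NIC or NNC chain had the most reads in both libraries, with at least 20 full-length reads in each.

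The groups, tests, 27 gene lists and most of the other settings tried were fixed before the data were examined. Named genes followed a rule fixed at the same time: up to 5 most abundant members of each list with its called members and any member of a neighbouring tissue above 50 CPM, the 10 most abundant genes, the 6 called genes with at least 50 reads that differed most each way, the 8 genes led by an unannotated form with the most reads, up to 6 called changes of form, up to 12 genes of a fixed set of isoform genes, 3 spliced antisense and 3 spliced intergenic genes, and the 10 genes with the most forms. The lists of pancreas acinar, pancreas islet, heat shock, brown fat and oxidative phosphorylation genes were written after values had been seen. So were the ribosomal RNA locus and the settings that leave out pancreas and liver genes, match lists on length, make classes equal between libraries, or leave out small differences from annotated chains.

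The code was tested on simulated counts drawn from the real means and totals with counting noise alone. The real libraries differed by more than counting noise, so the rates below test the code and are not error rates of these data. With 200 genes changed among 8110 to 8168 tested, the gene test recovered 44 of 200 at 2-fold, 126 at 3-fold, 170 at 4-fold and 199 at 8-fold, with 1 to 6 false calls. With no gene changed, 0 of 8130 were called. The call asks for at least 2-fold, so that many genes changed by just 2-fold must miss it at any depth: at 100 CPM or more, 24 of 56 were recovered. Simulated lists of 12 genes shifted by 1 on the log2 scale lay outside the random lists in 20 of 20 runs, and unshifted lists in 2 of 20. A change of form by 20 points was recovered in 165 of 200 genes.

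Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Other settings changed the scale, the minimum reads, the added CPM, the read classes, the depth, the treatment of mitochondrial genes and the matching of forms, and each library was left out in turn. Genome sequence outside annotated transcripts was not used here. Known input amounts of the spike-ins were not used here. Some genes that the rule names are not reported here.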

Results

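Long reads were collected from adrenal glands of male B6CASTF1/J mice aged 36 days, as 2 libraries of 1 group. The adrenal gland joins a cortex, which makes steroid hormones, to a medulla of chromaffin cells, which make catecholamines. Replicate 1 held 452489 endogenous reads and replicate 2 held 463210. They touched 13453 and 14138 annotated genes with at least 1 read, and 5973 and 6019 genes with at least 10. Values are read counts or CPM as mean ± SD (n = 2) unless a library is named. Tests on reads compare these 2 libraries, not conditions.

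The first question was what the gland expresses. Cyp11a1, the enzyme that starts steroid synthesis by cleaving the side chain of cholesterol, had the most reads of all classes together, at 25420 ± 2787 CPM (SD, n = 2), on chromosome 9 from 58006411 to 58027023. Cyp21a1, the steroid 21-hydroxylase (chromosome 17, 34801348 to 34804561), stood at 13103 ± 2219 CPM, and Star, which carries cholesterol into mitochondria (chromosome 8, 25806555 to 25815982), at 9349 ± 2612 CPM. Akr1b7 followed at 6498 ± 1618 CPM, Hsd3b1 at 6177 ± 529 CPM and Cyp11b1, the enzyme of the last step to corticosterone, at 5148 ± 408 CPM. The granins Chga and Chgb, stored in chromaffin granules, reached 4978 ± 1464 and 4359 ± 1398 CPM. The iron store subunit Fth1 (4116 ± 648 CPM) and the glycolytic enzyme Aldoa (4086 ± 63.0 CPM) complete the 10 most abundant genes over all classes, which together took 8.32% of endogenous reads. Of the Cyp11a1 reads, 49.6% in replicate 1 and 58.0% in replicate 2 were of the Genomic class. Over all genes, 98.2% and 98.0% of Genomic reads belonged to single-exon models. Over full-length reads (Known, NIC and NNC) the order turned, with 5790 and 4838 reads of Cyp21a1 against 5680 and 4168 of Cyp11a1. Hsd3b1 had 2964 and 2688 reads over all classes but 47 and 45 full-length reads, so its level rests on the other classes. Of its reads, 7.52% and 9.97% were of the Genomic class.

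The 22 steroidogenesis genes summed to 66281 ± 9925 CPM (SD, n = 2), with 20 members seen. The zona fasciculata list, markers of the inner cortex, summed to 14113 ± 2309 CPM, led by Akr1b7, Cyp11b1, the transporter Abcb1b (1781 ± 15.6 CPM), Mrap (599 ± 269 CPM) and the corticotropin receptor Mc2r (77.5 ± 0.261 CPM). Zona glomerulosa markers of the outer cortex summed to 4019 ± 1043 CPM, led by the potassium channel Kcnk3 (2757 ± 755 CPM), with the aldosterone synthase Cyp11b2 at 382 ± 153 CPM, Wnt4 at 356 ± 18.3 CPM, Agtr1a at 190 ± 46.4 CPM and Hsd3b6 at 133 ± 59.3 CPM. Of the X-zone markers, genes of the juvenile inner cortex, Akr1c18 had 3 reads in replicate 1 and 0 in replicate 2, Thrb had 0 and 2, and Pik3c2g had none, so X-zone transcripts were not detectable beyond a few reads at this depth. Chromaffin genes summed to 16704 ± 4261 CPM over 29 of 30 members. After Chga and Chgb came Th, the first enzyme of catecholamine synthesis (2540 ± 230 CPM), Scg2 (1336 ± 79.8 CPM) and the neuropeptide Npy (974 ± 399 CPM). Genes of cholesterol uptake and storage summed to 9823 ± 519 CPM, led by the lipoprotein receptor Scarb1 (3409 ± 574 CPM), Apoe (3144 ± 32.9 CPM), Lpl, Scp2 and Plin2. Cholesterol synthesis genes summed to 2665 ± 725 CPM, led by Dhcr7 (648 ± 140 CPM), Insig1, Fdps, Msmo1 and Hmgcs1.

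Genes of other cell types and tissues were also seen. Red blood cell genes summed to 4420 ± 566 CPM (SD, n = 2), led by Hba-a1, Hbb-bs, Hba-a2 and Hbb-bt. Hba-a1 and Hba-a2 are nearly identical copies, so the split of reads between them is uncertain. Fat genes summed to 10453 ± 321 CPM, led by Car3 (2939 ± 1045 CPM), Cfd, Fabp4, Cidea and Dgat2. Capsule and stroma genes summed to 2289 ± 426 CPM (led by Sparc, Col3a1, Dcn, Col1a1 and Fbln1), macrophage and antigen presentation genes to 1193 ± 62.1 CPM (Cd74, H2-Ab1, Lyz2, H2-Eb1 and C1qb), and endothelial genes to 963 ± 25.2 CPM (Plvap, Eng, Egfl7, Cldn5 and Emcn). Smooth muscle genes summed to 224 ± 63.9 CPM (Tagln, Acta2, Des, Mylk and Rgs5), Schwann cell genes to 49.0 ± 16.2 CPM (S100b, Mbp and Sox10) and lymphocyte genes to 32.8 ± 0.543 CPM (mostly Ighm). Antioxidant genes summed to 6742 ± 443 CPM, led by Gpx4, Prdx1, Mgst1, Prdx3 and Gpx3, and imprinted genes to 4329 ± 78.1 CPM, led by Gnas (1990 ± 16.5 CPM), Dlk1, Meg3, Cdkn1c and Ndn. Cell cycle genes summed to 221 ± 25.3 CPM, led by Mcm2, Pcna and Mcm6. The Y-linked Eif2s3y (31 and 25 reads) and Ddx3y (14 and 17 reads) were seen in both libraries and Xist in neither, as the male label states. Of the neighbouring kidney, Aqp2 alone had reads (8 and 2), and of skeletal muscle, Acta1 had 1 read in replicate 1 and Ckm 1 in replicate 2.

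The second question was how far the 2 libraries differ. Across 8135 genes with at least 10 reads summed, log2 levels had a Pearson correlation of 0.835 and a Spearman correlation of 0.856, where genes are not independent replicates. The biological coefficient of variation was 0.273. A chi-square of 33803 on 8134 degrees of freedom (4.16 per degree) exceeded what counting noise of independent reads gives. Amplified reads are not independent molecules, and the value does not tell separate animals from separate preparations of the same material. Fisher's exact test called 257 genes, 118 higher in replicate 2 and 139 higher in replicate 1, and 525 genes had an adjusted p under the threshold at any fold. Scaled by TMM factors, 254 genes were called, 140 higher in replicate 2 and 114 higher in replicate 1, with 232 shared.

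Digestive enzymes of the pancreas showed the widest differences in 1 direction. Clps, the lipase cofactor (chromosome 17, 28558149 to 28560766), had 542 reads in replicate 2 and 0 in replicate 1, at least 176-fold higher against a floor of 3 counts in replicate 1. Try4 (at least 171-fold), Cela2a (at least 153-fold), Ctrb1 (at least 127-fold), Prss2 (at least 111-fold) and Amy2a5 (at least 106-fold, from 324 reads against 0) followed. Try4 and Prss2, and the amylase copies beside Amy2a5, are near-identical relatives whose shares of reads are uncertain. The list of 21 pancreas acinar genes was written after these values were seen. All 21 members were called higher in replicate 2, from 40 reads in replicate 1 to 4650 in replicate 2, and the list median was 8.06 on the log2 scale, or at least 5.32 with members at 0 set to their bound. Cela1 held 34 of the 40 reads of replicate 1, against 314 in replicate 2 (9.02-fold, exact 95% interval 6.32 to 13.3). Of the pancreas islet genes, also listed afterwards, Ins2 (0 and 91 reads, at least 29.6-fold) and Ins1 (0 and 23 reads, at least 7.49-fold) were called. Liver genes, listed beforehand, went the same way: all 6 tested members were called higher in replicate 2, and 6 adjusted over the list alone, with a median of 5.84 or at least 3.78. Apoa1, the main protein of high-density lipoprotein, stood at 69.1 ± 94.6 CPM (SD, n = 2), from 1 read and 63 reads (61.5-fold, exact 95% interval 10.7 to 2469). Apoa2, Alb, Ttr and Serpina1c had 0 reads in replicate 1 and 46, 42, 35 and 18 in replicate 2, and Mup3 had 2 and 34 reads (16.6-fold, 4.26 to 143). Without the pancreas and liver lists, the ribosomal RNA locus and 1 call whose place held as many reads under another gene, 226 calls were left, 88 higher in replicate 2 and 138 higher in replicate 1. This leaves out listed genes alone, and other liver and pancreas genes, such as Fabp1 (0 and 24 reads), Mup7 (0 and 43 reads) and the amylase copy Amy2b (0 and 147 reads), singled out after their values were seen, stayed among the 88. The check of place asked for at least as many reads as the gene's leading model, on the same strand, so it misses partial cases. Klhl10 (41 and 0 reads), with 32 reads under another gene at its place in replicate 2, stayed among the 138.

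Immediate early genes, which are switched on within minutes of a stimulus, were higher in replicate 1. All 12 tested members of the list had the lower value in replicate 2, with a median log2 ratio of -1.15 (percentile 0 among the random lists). Called were 5, and 6 adjusted over the list alone, with Klf2 (40 and 18 reads) in addition. Nr4a1, an orphan nuclear receptor (chromosome 15, 101254269 to 101274795), had 519 reads in replicate 1 and 8 in replicate 2, a 66.4-fold difference (exact 95% interval 33.5 to 155). Nr4a2 had 24 and 1 reads (24.6-fold, 4.01 to 1010), Btg2 19 and 1 (19.5-fold, 3.09 to 808), Junb 67 and 21 (3.27-fold, 1.98 to 5.62) and Ier2 67 and 27 (2.54-fold, 1.60 to 4.13). The abundant members Jund (771 ± 309 CPM, SD, n = 2) and Jun (495 ± 203 CPM) did not reach 2-fold. Of the glucocorticoid response list (median -0.68, percentile 0.05), Tsc22d3 (81 and 35 reads) and Errfi1 (49 and 10 reads) were called higher in replicate 1, and 2 were adjusted over the list alone. Its most abundant members Mt1, Pdk4, Mt2 and Sgk1 were not called. In the circadian clock list (median -0.04, percentile 45.7), led by Dbp, Nr1d1, Bhlhe40, Tef and Cry1, only Per2 was called, with 20 and 3 reads (6.82-fold, 2.02 to 35.9), and 1 adjusted over the list alone.

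The steroidogenesis, zona glomerulosa and cholesterol synthesis lists were lower and the chromaffin list higher in replicate 2, while the zona fasciculata list lay inside the random lists (median -0.16, percentile 25.1). The steroidogenesis median was -0.34 (percentile 0.23), with 12 of 17 tested members lower, and only the steroidogenic regulator Nr5a1 was called, at 274 and 129 reads (1 adjusted over the list alone). The zona glomerulosa median was -0.53 (percentile 0.71) with none called, and none adjusted over the list alone. Of 22 cholesterol synthesis genes, 19 were lower in replicate 2, with a median of -0.58 (percentile 0.01). Idi1 (43 and 14 reads) and Sqle (42 and 12 reads) were called, and 5 adjusted over the list alone, among them Mvd. Chromaffin genes had a median of 0.52 (percentile 99.99), with 21 of 25 higher in replicate 2, and the secretory granule gene Resp18 was called at 26 and 64 reads (1 adjusted over the list alone). Chga and Chgb differed by 0.61 and 0.67 on the log2 scale and did not reach 2-fold.

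Transcripts of the mitochondrial genome were higher in replicate 2 in 11 of 11 tested genes (median 0.90, percentile 100). mt-Cytb, mt-Nd2, mt-Co2 and mt-Rnr2 were called, and 4 adjusted over the list alone, while mt-Co1, the most abundant, and mt-Nd1 were not. Ribosomal protein genes were higher in 75 of 82 (median 0.34, percentile 100, or 99.3 against lists matched on length as well), none of them called and none adjusted over the list alone. Rpl41, Rplp0, Rpl13 and Rps14 were among the most abundant. Beside these shifts, the 1609 genes with the shortest transcripts, up to 1387 bases, had a median log2 ratio of 0.21, while the 4 groups of longer transcripts had medians of -0.13, -0.22, -0.14 and, for the longest, -0.03. Reads at the ribosomal RNA locus (chromosome 17, 39843013 to 39848827) took 0.233% of reads in replicate 1 and 1.16% in replicate 2. In the adipose list (median -0.07, percentile 34.7) Ucp1 was called higher in replicate 2, at 198 and 437 reads, and in the red blood cell list (median -0.25, percentile 14.3, or 0.86 against lists matched on length as well) Alas2 was called higher in replicate 1, at 26 and 6 reads. Each was the 1 member adjusted over the list alone. The macrophage median of 0.29 lay at percentile 97.6, and at 84.5 against lists matched on length. Cholesterol uptake and storage (1 adjusted over the list alone), capsule and stroma, endothelial, smooth muscle (-0.77, percentile 2.72), proliferation, antioxidant and imprinted genes lay inside the middle 95% of random lists with none called over all genes, and for the other lists named here none adjusted over the list alone.

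Among called genes with at least 50 reads summed, ranked by log2 ratio with 1 CPM added, those higher in replicate 1 were led by Gm7247 (133 and 0 reads, at least 45.4-fold) and Gm43126 (126 and 0 reads, at least 43.0-fold), an order that rests on the added CPM, since the measured fold of Nr4a1 is above both bounds. All reads of both were of the Genomic class. The place of Gm43126 held 148 reads under another gene in replicate 2, so that difference is one of gene assignment. Nr4a1 came next, then Grasp (87 and 8 reads), the heat shock gene Hspa1b (132 and 14 reads, a near-identical copy of Hspa1a) and 2010109I03Rik (243 and 27 reads).

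**Figure D1:**
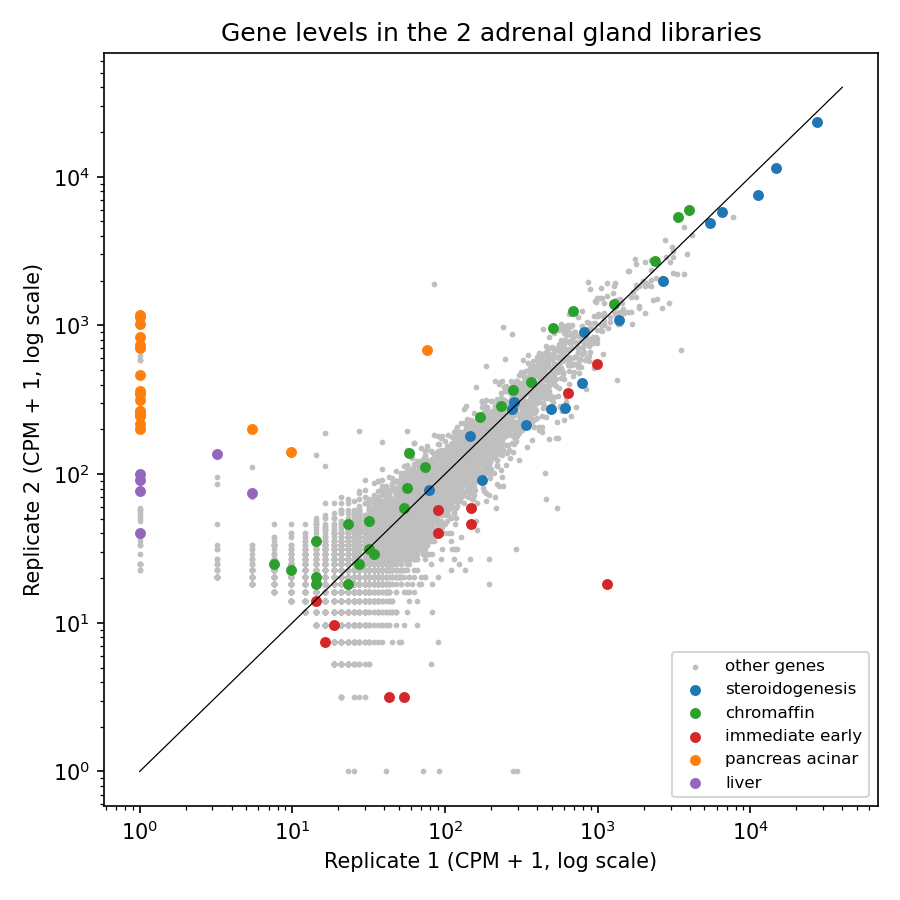
Level of each of the 8135 genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), as CPM + 1 on log scales, with the line of equal levels; coloured points are members of 5 gene lists and grey points all other genes. Pancreas acinar and liver genes lie at or near 0 CPM in replicate 1, apart from Cela1, and the 12 tested immediate early genes lie below the line.

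**Figure D2:**
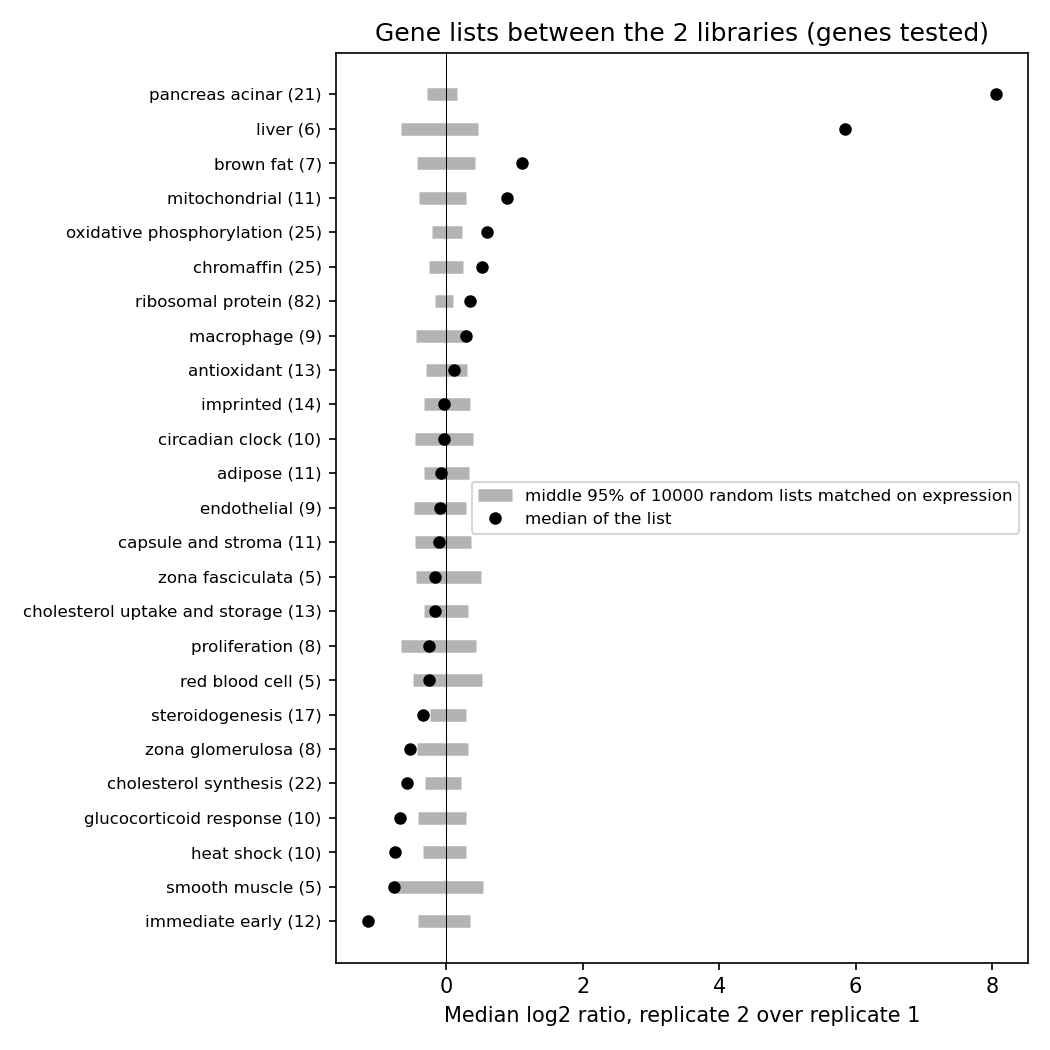
Median log2 ratio of replicate 2 over replicate 1 for each list with at least 5 tested genes (black points, number of genes in brackets), with the middle 95% of 10000 random lists matched on expression (grey bars). The pancreas acinar, heat shock, brown fat and oxidative phosphorylation lists were written after values had been seen, so their place against random lists is no test. The medians of 8.06 for pancreas acinar and 5.84 for liver depend on the 1 CPM added to genes with 0 reads, and the immediate early list lies lowest at -1.15.

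The third question was what kinds of transcripts the long reads hold. Known transcripts took 74.4 ± 1.73% of endogenous reads (SD, n = 2), with Wilson 95% intervals of 75.5 to 75.7% in replicate 1 and 73.0 to 73.3% in replicate 2. ISM took 8.17 ± 0.393%, Genomic 5.55 ± 0.665%, Antisense 4.27 ± 1.15%, NIC 3.70 ± 0.50%, NNC 3.09 ± 0.159% and Intergenic 0.839 ± 0.176%. Each share differed between the libraries in Fisher's exact test, the least clearly NNC (adjusted p = 5.55e-10), with Known, NIC and NNC lower and ISM, Genomic, Antisense and Intergenic higher in replicate 2. The read-weighted median length of the models was 1850 bases in replicate 1 and 1574 bases in replicate 2, and 1883 and 1716 bases over Known transcripts.

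In most genes 1 form took nearly all full-length reads. Over 1321 genes, the median share of the leading form was 94.8 ± 0.152% (SD, n = 2), the same form led in both libraries in 1298 genes (98.3%), and 48 genes had a leading share under 50% in both. Gnas, which encodes the stimulatory G protein subunit, was split between Gnas-208 (60.5 ± 0.851%), Gnas-207 (21.9 ± 0.743%) and Gnas-206 (10.3 ± 0.150%). Pkm, pyruvate kinase, was led by Pkm-201 (66.6 ± 3.30%) over Pkm-202 (27.1 ± 3.52%), Dlk1 by Dlk1-205 (69.7 ± 2.27%) over Dlk1-208 (20.1 ± 0.822%) and Atp5c1 by Atp5c1-203 (78.7 ± 1.42%) over Atp5c1-201 (39 and 38 reads). Of the steroid genes among the 1321, the annotated main form led with 94.9 ± 1.58% for Cyp11a1, 94.2 ± 0.670% for Cyp11b1, 93.7 ± 1.46% for Cyp21a1 and 83.3 ± 1.14% for the reductase Fdxr. Hsd3b1, with 47 and 45 full-length reads, was below the minimum of 50. An NNC form led it in both libraries (17 and 16 reads, 35.9 ± 0.435%), against 12 and 14 reads of Hsd3b1-201. Scarb1-201 took 92.8 ± 0.491% and Apoe-206 97.6 ± 0.0521%. The leading form of Akr1b7 took 94.7 ± 3.33%, and its NIC form on chromosome 6 from 34412334 to 34423524 had 163 reads in replicate 1 and 1 in replicate 2. Most forms of at least 5 reads in each library were counted for Cyp21a1 (11, of which 10 unannotated), Cyp11a1, Chga, Pcyt2 and Meg3 (7 each). Cyp11b1, Aldoa, Scarb1, Gnas and Slc25a3 had 5 each, as had 7 further genes. A fixed minimum of reads lets such counts rise with depth. Cyp21a1 had 5790 and 4838 full-length reads, of which its second form held 0.442%, while Meg3 had 130 and 122.

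Usage of the leading form differed between the libraries in 3 of 1226 genes by Fisher's exact test. Th-201 of Th held 84.8% of reads in replicate 1 (Wilson 95% interval 82.5 to 86.9%) and 96.2% in replicate 2 (94.9 to 97.1%), a difference of 11.3 points (adjusted p = 4.86e-18, Fisher's exact test). Its next form, a NIC chain with 11 exons in place of 13, had 43 and 3 reads. That form is 2520 bases long against 1829 for Th-201 over the same span, so it keeps intron sequence that Th-201 lacks. The call for Cyb561 came from naming: its leading chain was classed NIC with 88 reads in replicate 1 and ISM with 104 reads in replicate 2, and with classes made equal between the libraries 2 calls were left, Th among them. Such changes of class affected 502 of 20189 chains found in both libraries (2.49%).

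In 65 of 3030 genes (2.15%) the same unannotated form led in both libraries. Oaz1 (NIC form, chromosome 10, 80826656 to 80829285) had 877 and 850 reads, 96.2 ± 0.752% of its full-length reads (SD, n = 2), and Oaz2 (129 and 82 reads) 88.1 ± 3.84%. Both differ from an annotated form only by an annotated intron, of 4 and 1 bases. The aligned chain of the lead form lacks an annotated exon of 4 bases in Mpc1 (93.2 ± 2.42%), of 12 bases in Idh3g (80.8 ± 1.49%), of 19 bases in Mrpl33 (89.8 ± 0.431%) and of 6 bases in Phb2 (97.4 ± 1.37%). In Ctbp1 (59.5 ± 0.662%) 1 junction lies 3 bases away. In Idh3g and Mrpl33 the intron over the missing exon also has 1 end that is not annotated. Whether the transcripts themselves lack the bases of these exons was not tested. Small differences of these kinds, of up to 20 bases, accounted for 33 of the 65 genes (3 by an annotated intron, 16 by an annotated exon and 14 by a shifted junction), and 32 were left. The most abundant of the 32 was Srd5a2, a steroid 5-alpha-reductase (chromosome 17, 74016955 to 74047916, minus strand). Its NNC form had 688 and 612 reads, 51.0 ± 2.46% of full-length reads, against 571 and 565 reads of the annotated Srd5a2-201. Its intron chain differs by a gap of 59 bases, from 74017151 to 74017209, in the annotated 3' untranslated region. The model also runs past the annotated end of the gene, to 74014891.

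Whether an unannotated intron chain was found again depended on its reads. Of chains with 1 read, 45.2 ± 1.11% of Known, 22.1 ± 0.503% of ISM, 19.4 ± 2.44% of NIC and 11.3 ± 0.520% of NNC chains were found in the other library (SD, n = 2). At 5 to 19 reads the shares were 98.3 ± 0.510% for Known, 94.1 ± 2.71% for ISM, 96.1 ± 2.43% for NIC and 95.0 ± 0.480% for NNC. Spliced antisense genes were shared by both libraries in 77 cases, led by genes opposite Mc2r (chromosome 18, 68407568 to 68429320, 66 and 101 reads), Mbnl1 (chromosome 3, 60529549 to 60595749, 47 and 74 reads) and Crebbp (chromosome 16, 4128444 to 4213997, 49 and 37 reads). Spliced intergenic genes were shared in 31 cases, led by places on chromosome Y (43918756 to 43923020, 29 and 19 reads), chromosome X (32502591 to 32507553, 25 and 9 reads) and chromosome 10 (45065131 to 45067203, 15 and 15 reads). The chromosome 10 place lies opposite the annotated gene Prep although its class is Intergenic, and its spliced form had 1 read in each library.

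**Figure D3:**
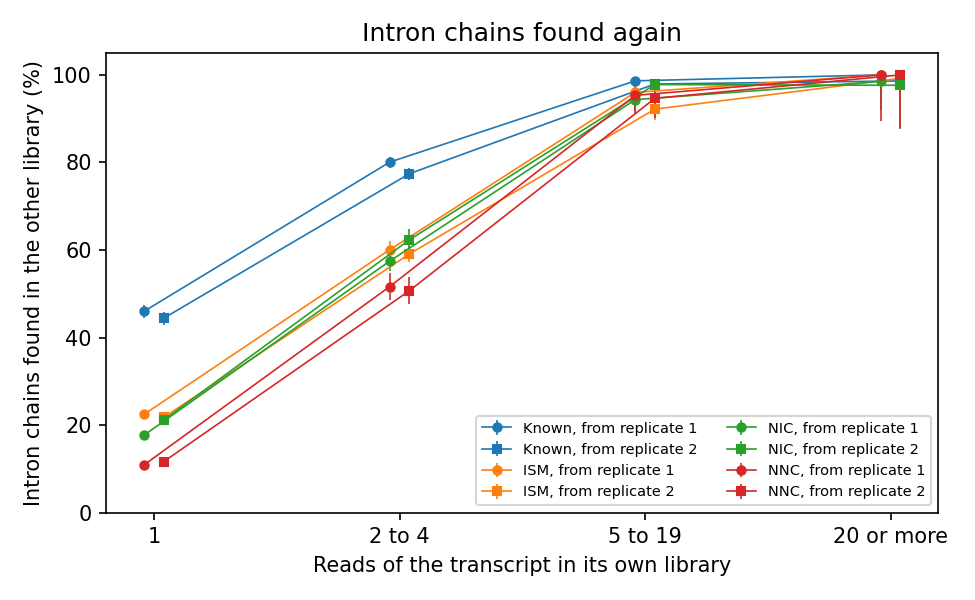
Share of intron chains of 1 library found in the other (vertical axis, %) by their reads in their own library (horizontal axis), per class and per library, with Wilson 95% intervals. The share lies between 10.9% and 46.0% at 1 read and between 92.2% and 98.6% at 5 to 19 reads.

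Spike-in transcripts of the ERCC set took 1.20% of all reads in replicate 1 (Wilson 95% interval 1.17 to 1.24%) and 3.30% in replicate 2 (3.25 to 3.35%), a ratio of 2.74. The 36 found in both libraries correlated at 0.982 (Pearson) and 0.963 (Spearman) in log2 reads across transcripts, which are not independent replicates. Over the 28 with at least 10 reads, 505 to 1156 bases long, the log2 ratio of the libraries had a Pearson correlation with log length of -0.273 (permutation p = 0.165) and a Spearman correlation of -0.177 (permutation p = 0.364), 2 tests of 1 family of which neither passed, and -0.327 without the 2 farthest from the median length.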

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

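The settings that leave out the pancreas and liver lists or a call whose place held as many reads under another gene, match lists on length, make classes equal, leave out forms close to annotated chains, or keep Known transcripts alone were chosen after the results were seen, and the others before the data were examined. Of 66 values of the main results under other settings, 51 stayed close and 15 moved further. Close meant within the SD of the libraries, within 1.5 times a count or coefficient of variation, or within the 95% interval of the correlation across genes. The 51 include shares, sums and lengths with 1 library left out, which must stay within the SD. They also include the share of ERCC spike-ins alone, which is the same value as all spike-ins. The split of calls turned: 118 genes were higher in replicate 2 and 139 in replicate 1, against 120 and 117 with DESeq2 size factors, 140 and 114 with TMM factors, and 110 and 102 with Known, NIC and NNC reads. The share of Known reads was 78.5% within genes of the reference annotation and 83.8% without single-exon transcripts, both by construction, since these leave out classes that hold unspliced reads. The correlation between the libraries was 0.774 with 0.1 CPM added, 0.852 with no minimum of reads and 0.871 without the pancreas and liver lists and the ribosomal RNA locus. At 1.5-fold, 399 genes were called. Steroidogenesis genes summed to 50359 CPM over Known, NIC and NNC reads alone. These leave out the Genomic reads of Cyp11a1 and most reads of Hsd3b1, which had 47 and 45 full-length reads out of 2964 and 2688. The median share of the leading form was 89.9% with ISM reads in the denominator, 96.9% at 200 reads or more and 94.5% over multi-exon forms. Genes led by an unannotated form numbered 25 at 50 reads, 41 with NIC forms alone and 32 without forms within 20 bases of an annotated chain. Of unannotated chains, 96.1% were found in the other library at 5 reads or more and 18.6% when both ends had to match within 50 bases, against 23.8% otherwise. Where no construction is named, the cause was not tested.

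With each library left out in turn, the Known share ranged from 73.2 to 75.6%, genes detected from 13453 to 14138, the steroidogenesis sum from 59263 to 73299 CPM, the leading share from 94.7 to 95.0%, the spike-in share from 1.20 to 3.30% and the median model length from 1574 to 1850 bases. With 2 libraries, leaving out 1 always moves a mean by the same part of the spread, so these ranges say nothing about stability. Genes led by an unannotated form numbered 89 to 94, above the 65 of both libraries by construction, since the lead and the minimum of reads must hold in both. Without the need for the same form in both, 67 were counted. Of 144 shifts of lists under other settings, among them lists written after values had been seen, 131 kept their direction and their side of the middle 95% of random lists. Medians close to 0 changed sign in 6, all inside it: the circadian clock list to 0.0294 with TMM factors and 0.0244 with Known, NIC and NNC reads, the imprinted list to 0.0385 with TMM factors and 0.000344 with totals that leave out pancreas, liver and ribosomal RNA genes, and the adipose list to 0.0271 with Known, NIC and NNC reads and 0.0159 at 50 reads. The macrophage list fell inside it under 4 settings, the smooth muscle list outside it under 2, and the red blood cell list outside it when length was matched. Spike-ins of the SIRV set gave no value and are not analysed here. No paired analysis was possible because there is 1 group. Depth limits genes near the floor of 3 counts.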

Other observations

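The lists of brown fat, oxidative phosphorylation and heat shock genes, their shifts, and the tests of explanations that follow were chosen after the results were seen, except the test of the ends of the Srd5a2 gap. The test of each gene was fixed before the data were examined. Since these lists were chosen for the pattern, their medians are descriptions, and a place among random lists cannot serve as a test of them. Brown fat genes were higher in replicate 2 in 7 of 7 tested members (median 1.11 on the log2 scale). Fisher's exact test called 4, and 5 adjusted over the list alone: Cox8b (393 and 908 reads), Cox7a1 (112 and 275 reads), the uncoupling protein Ucp1 (198 and 437 reads), Elovl3 (2 and 51 reads, 24.9-fold, exact 95% interval 6.55 to 211) and, over the list alone, Fabp3 (14 and 30 reads). Ucp1 and Cidea also belong to the adipose list, whose median stood at -0.07. Oxidative phosphorylation genes were higher in replicate 2 in 25 of 25, with a median of 0.60 and none called, led by Cox4i1 (3270 ± 703 CPM, SD, n = 2), Uqcrq, Cox8a, Ndufa4 and Cox6a1. These are short transcripts, with a median length of 572 bases, and the 1609 genes with the shortest transcripts had a median of 0.21. Against random lists matched on length as well, the list lay at percentile 100. The list was chosen for the pattern, and the shortest of the 5 length bins runs from 61 to 1387 bases. This percentile therefore does not exclude length as a source of the median. Heat shock genes went both ways, with 6 of 10 higher in replicate 1 and 4 higher in replicate 2 (median -0.76). Called higher in replicate 1 were 5: Hspa1b, Dnajb1 (87 and 12 reads), Hspa1a (65 and 12 reads), Bag3 (101 and 38 reads) and Hspa8 (1331 and 659 reads). Hspa1a and Hspa1b are near-identical copies. Alas1, the first enzyme of haem synthesis, was singled out after its values were seen: 1593 and 317 reads, a 5.14-fold difference (4.56 to 5.82).

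Pancreas and liver transcripts were present in replicate 2 and, apart from Cela1 with 34 reads, had few or no reads in replicate 1. Mixing in of libraries from many other tissues would bring kidney and skeletal muscle transcripts too, and these lists had 3 reads in replicate 2 against 9 in replicate 1, which argues against it. Tissue of pancreas and liver carried along at dissection stays open and was not decided by a test: 32 of the 34 listed genes had reads in replicate 2 and 5 had reads in replicate 1, but the pancreas genes were listed because of these reads, and reads of a pancreas and a liver library alone cannot be told apart from it here. The most abundant were Clps with 542 reads and Try4 with 525. No biological explanation was tested, since the design has 1 group.

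Immediate early genes were higher in replicate 1. A bias for transcript length would place the list within the random lists once length is matched, but its percentile was 0.0 there. Reads placed under another gene in replicate 2 numbered 0 on the strand of the 5 called members, against 654 reads missing. This argues against placement under another gene on that strand. Reads on the opposite strand were not counted. A difference between the samples in handling or in the time of collection stays open and was not tested, since the labels give neither.

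The gap of 59 bases in the 3' untranslated region of Srd5a2 (chromosome 17, 74017151 to 74017209) was counted among reads of multi-exon models that span the place. It was carried by 55.3% of these reads in replicate 1 (749 of 1354, Wilson 95% interval 52.7 to 57.9%, exact binomial p against equal shares 0.000100). In replicate 2 it was carried by 51.8% (678 of 1310, 49.0 to 54.5%, exact binomial p = 0.214). Counts are per model, so a read that ends before the place may be counted as lacking the gap. Shares among reads that cover the place were therefore not measured. A spliced intron of the usual kind is a candidate explanation: 1 of the 4 placements that the edge bases allow has GT-AG ends. The gap was examined because the pipeline recorded it as an intron, and whether that step favours such ends was not tested. A deletion on 1 parental allele of the hybrid, aligned as an intron, is the other. The mean share over reads of models that span the place was 53.5%, inside the range of 40 to 60% set for a deletion. Splicing can give any share, and the share among reads that cover the place is not known, so this does not tell the explanations apart. Sequence of the CAST/EiJ strain was not used here, and both stay open.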
